A study of Homo sapiens with 6 samples.

How the data were processed

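The series holds 6 RNA sequencing libraries of HK-2 cells, 3 with empty vector and 3 with a circAASS overexpression plasmid, all after 1% oxygen for 24 h and reoxygenation for 12 h. Groups and repeat numbers were taken from the sample titles and oxygen and times from the treatment label. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as read pairs on a NovaSeq instrument, and overexpression of circAASS had been checked before hypoxia. The series' design text dates the profiling to 24 h after hypoxia and reperfusion, whereas the sample labels give 12 h of reoxygenation; the labels' time is used here.

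The deposited values were RPKM, that is reads scaled to the length of the gene and to the size of the library, in a table of 35035 genes with 1 column per library; no column was left unmatched to a library. The submitters' processing notes name Trimmomatic 0.36 for trimming, featureCounts and Subread 1.5.1 for counting, edgeR 3.12.1 and the genome build GRCh38. The aligner and the version of the gene annotation are not given in the sources used here, nor is whether the counting used strand. Reads of genes that overlap, lie antisense or have near-identical copies can therefore have been counted for the wrong gene or left out, and the report names as uncertain the genes of which other genes in GENCODE 29 cover at least 20% of the exon bases on either strand. Of the other genes named, 10% to 20% are so covered in CDH6, CLDN2, FGFBP3, CPT2, RPL23A, UCA1, ETFDH, JUNB, TTLL1, KRT18, ROBO4, MT1X and IGFBP7, whose reads are uncertain to that extent. The overlaps of DFNA5 and RNA5-8S5 were not examined. Names of 28 genes had been turned into dates, as spreadsheet software does, and these genes were left out of all tests.

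Whole reads were worked out from the RPKM. For 24697 genes whose name occurs once in GENCODE 29 (GRCh38), the union of exons gave a length; with it, values in all 6 libraries were whole multiples of 1 read, within 0.02 reads, for 22385 genes (90.6%). For the other 12650 genes the smallest length that made all values whole was used, so that their reads are less certain. Of the tested genes, 14046 had the annotated length and 5304 a length found in this way. The recovered reads added up to 99.90% to 99.91% of the library totals of 45148425 to 58179563 reads. Of read numbers from 1 to 20, 78.6% were even, since mates of a pair were mostly counted separately; counting error is thus larger than the read numbers imply. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.03 to 4.15 with empty vector and 7.32 to 12.01 with the circAASS plasmid, so none was a copy of another.

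The design fixed before the data were examined named edgeR's quasi-likelihood test for counts, which was not used because the values proved to be RPKM. In its place limma 3.58.1 (R 4.3.3) tested log2(RPKM + 0.1), with an intensity trend in the prior variance and robust estimation, and the 2 groups as the sole term. Fold changes are on this log2(RPKM + 0.1) scale and understate the change of low genes. RPKM were scaled with trimmed-mean factors (30% of ratios and 5% of levels trimmed) computed from the recovered reads; these were 1.018, 1.023 and 1.036 with empty vector and 0.958, 0.971 and 0.996 with the circAASS plasmid. Genes were tested with at least 10 reads at the median library size in at least 3 libraries and 15 reads in all. P-values are two-sided and Benjamini-Hochberg adjusted over the tested genes, with a threshold of 0.05; means ± SD are of the deposited RPKM over 3 libraries. Figures were drawn with matplotlib 3.10.9, and reads and annotation were handled in Python 3.11 with numpy 2.4.6 and pandas 2.3.3.

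Genes were named by a rule set before the data were examined: AASS; the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and groups that did not overlap; the 5 smallest p in each direction; and up to 4 members with the smallest p of each list that passed or is described. A symbol was taken to be a gene name in the reference table of names, other than a name made from a clone. Results of a few list members are not reported here. Other genes are said to have been chosen after their values were seen. Positions are those of GENCODE 29 on GRCh38, the build of the submitters' notes, counted from 1.

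The 32 gene lists were also fixed before the data were examined. They cover lysine degradation, targets of the hypoxia-inducible factors, tubular injury, proximal tubule identity, NF-kB and inflammation, the interferon response, antigen presentation, p53 targets, apoptosis, pyroptosis and necroptosis, ferroptosis, NRF2 targets, ATF4 targets, the unfolded protein response, mitophagy and autophagy, the mitochondrial genome, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, S phase, G2 and M phase, epithelial-mesenchymal transition and fibrosis, epithelial junctions, YAP and TEAD targets, immediate-early genes, heat shock, replication histones, cytosolic ribosomal proteins, and markers of fibroblasts, endothelium, leukocytes and the distal nephron. Lists with at least 5 tested members were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. They were tested again with an estimated correlation and with fry.

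The tests were tried on simulated reads drawn for 19321 genes from the means and library sizes of the comparison, with 200 genes changed. They recovered 1 of 49 genes changed 1.25-fold (2.04%), 24 of 49 changed 1.5-fold (49%), 32 of 49 changed 2-fold (65.3%) and 44 of 50 changed 4-fold (88%). Of the calls, 10 (9.01%) were unchanged genes, which is above the nominal 5%. In the data a far larger share of genes was called (32.26% of those tested), which eases the adjusted threshold. The recovered and false shares of the simulation therefore do not carry over to the data. None of 30 unchanged lists was called and a list of 30 members raised 1.25-fold was called. The simulated genes were drawn independently of each other, whereas the estimated correlation reached 0.655 in the ribosomal protein list. The simulation therefore does not show how often lists of correlated genes are called wrongly.

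The alternatives were median-of-ratios, upper-quartile and library-size scaling; no filter on low counts and a filter at 1 CPM in 3 libraries; limma-voom on the recovered reads; fits without robust estimation; other thresholds; genes over 1% of counts left out; a replicate block; and each library left out in turn. Added after seeing the data were pseudocounts of 0.02, 0.5 and 1 RPKM, a mean of at least 1 RPKM, and removal of a GC and length trend with and without the block. A GC value was found for 80.3% of the tested and 84.3% of the changed genes.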

Results

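RNA sequencing libraries were made from HK-2 cells, an immortalised line of human kidney proximal tubular epithelial cells. The cells had been transfected with a plasmid for overexpression of circAASS or with the empty vector. circAASS is, by its name, a circular RNA of the gene AASS; circular RNAs are closed loops without a poly(A) tail. Each group had 3 libraries. The cells of all 6 libraries were kept at 1% oxygen for 24 h and then reoxygenated for 12 h, a cell model of kidney ischaemia and reperfusion, and no library from cells kept at normal oxygen was analysed here. The deposited values were RPKM per gene. Library totals were 45148425, 51014541 and 52470055 reads with empty vector and 47966937, 58179563 and 47384879 with the circAASS plasmid, mates of a read pair counted separately. Genes of the mitochondrial genome took 9.04%, 8.87% and 8.94% of the reads with empty vector and 9.46%, 10.06% and 9.10% with the circAASS plasmid. The labels state no separate passages or days for the repeats, so the p-values measure the spread between these libraries only, which may be technical.

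AASS, which encodes the enzyme of the opening steps of lysine degradation, was the host gene of the overexpressed RNA (chromosome 7, 122075647 to 122144280, GRCh38). It stood at 1.20, 1.38 and 1.1 RPKM in the empty-vector libraries, from 249, 323 and 265 reads. It stood at 0.836, 0.977 and 0.827 RPKM in the circAASS libraries, from 184, 261 and 180 reads. The means were 1.23 ± 0.141 and 0.880 ± 0.0842 (SD, n = 3 each). The log2 fold change of -0.37 (SE 0.13) did not pass the test over all genes (limma, Benjamini-Hochberg adjusted p = 0.0677). It passed with scaling by library size alone, where the log2 fold change was -0.44 and the adjusted p = 0.0383, and with some other settings; over all settings tried the adjusted p ran from 0.034 to 0.203. A library of poly(A) RNA summed per gene does not separate circular from linear or plasmid-derived RNA, so these values are those of the host gene and do not check the labels. circAASS itself was not matched by identifier or coordinates and has no value here.

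The question of the comparison was which transcripts differ between cells given the circAASS plasmid and cells given empty vector after hypoxia and reoxygenation. The secreted pattern-recognition protein PTX3 had the largest rise of the genes named by the rule, from 7.11 ± 0.586 to 64.0 ± 6.30 RPKM (chromosome 3, 157436789 to 157443628). Its log2 fold change was 3.22 (SE 0.09, adjusted p = 2.07e-05). AKR1B1, the aldose reductase that makes sorbitol, rose from 114 ± 7.71 to 393 ± 32.5 RPKM (chromosome 7, 134442350 to 134459284; log2 fold change 1.86, SE 0.07). SLC5A3, a sodium-coupled myo-inositol transporter, rose from 3.39 ± 0.216 to 14.3 ± 2.17 RPKM (chromosome 21, 34073570 to 34106262; log2 fold change 2.11, SE 0.10). F3, tissue factor, rose from 7.51 ± 0.138 to 22.1 ± 1.98 RPKM (chromosome 1, 94529225 to 94541800; log2 fold change 1.61). The Wnt antagonist DKK1 rose from 1.87 ± 0.093 to 7.29 ± 0.559 RPKM (chromosome 10, 52314296 to 52318042; log2 fold change 1.98). The other rises named by the rule were the long non-coding RNA UCA1 (3.36 to 18.8 RPKM), SERPINB7 (1.43 to 7.04), TMEM171 (2.04 to 8.17), LURAP1L (0.819 to 3.83), PALM3 (0.865 to 4.20), PRSS35 (0.123 to 0.930) and CALB2 (0.167 to 1.15), with log2 fold changes between 2.01 and 2.53. All of these passed with adjusted p of at most 0.00402. SLC5A3 shares 2.4% of its exon bases with MRPS6 and another gene on the same strand, and MRPS6 itself went from 9.61 to 29.5 RPKM.

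MT2A, an abundant zinc- and copper-binding metallothionein, fell from 689 ± 56.1 to 260 ± 5.61 RPKM (chromosome 16, 56608199 to 56609497; log2 fold change -1.33, SE 0.06, adjusted p = 8.00e-05). MT1E, its neighbour, fell from 15.2 ± 2.05 to 2.47 ± 0.228 RPKM (chromosome 16, 56625475 to 56627112; log2 fold change -2.50, SE 0.10). Near-identical copies make the split of reads among metallothioneins uncertain. CDH6, a cadherin of the proximal tubule, fell from 13.5 ± 0.269 to 4.89 ± 0.256 RPKM (chromosome 5, 31193750 to 31329146; log2 fold change -1.37, SE 0.05). TK2, the thymidine kinase of mitochondria, fell from 5.34 ± 0.125 to 1.95 ± 0.113 RPKM, and other genes lie antisense to 21.9% of its exon bases. The antisense transcript FLJ16779 fell from 1.53 ± 0.112 to 0.125 ± 0.0332 RPKM (chromosome 20, 63253978 to 63261615; log2 fold change -2.81), and ZMAT1 from 10.4 ± 1.04 to 1.81 ± 0.0878 RPKM (log2 fold change -2.39). The remaining falls named by the rule were TEX19 (1.83 to 0.359 RPKM), SLC16A9 (0.561 to 0.0700), AHNAK2 (9.44 to 2.36), SULT1C2 (3.07 to 0.731), TTLL1 (2.68 to 0.708), SLC24A1 (2.37 to 0.604) and FGFBP3 (0.738 to 0.146), with log2 fold changes between -1.71 and -2.01. All passed with adjusted p of at most 0.00142. An antisense gene covers 43.8% of the exon bases of TEX19. Fold changes of low genes shrink with the pseudocount: with 1 RPKM in place of 0.1, that of CALB2 was 0.91, that of PRSS35 0.80, that of PALM3 1.53 and that of LURAP1L 1.45. In the falls it was -1.14 for FLJ16779, -1.02 for TEX19, -0.53 for SLC16A9, -0.58 for FGFBP3, -1.19 for SULT1C2, -1.07 for TTLL1 and -1.03 for SLC24A1.

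**Figure D1:**
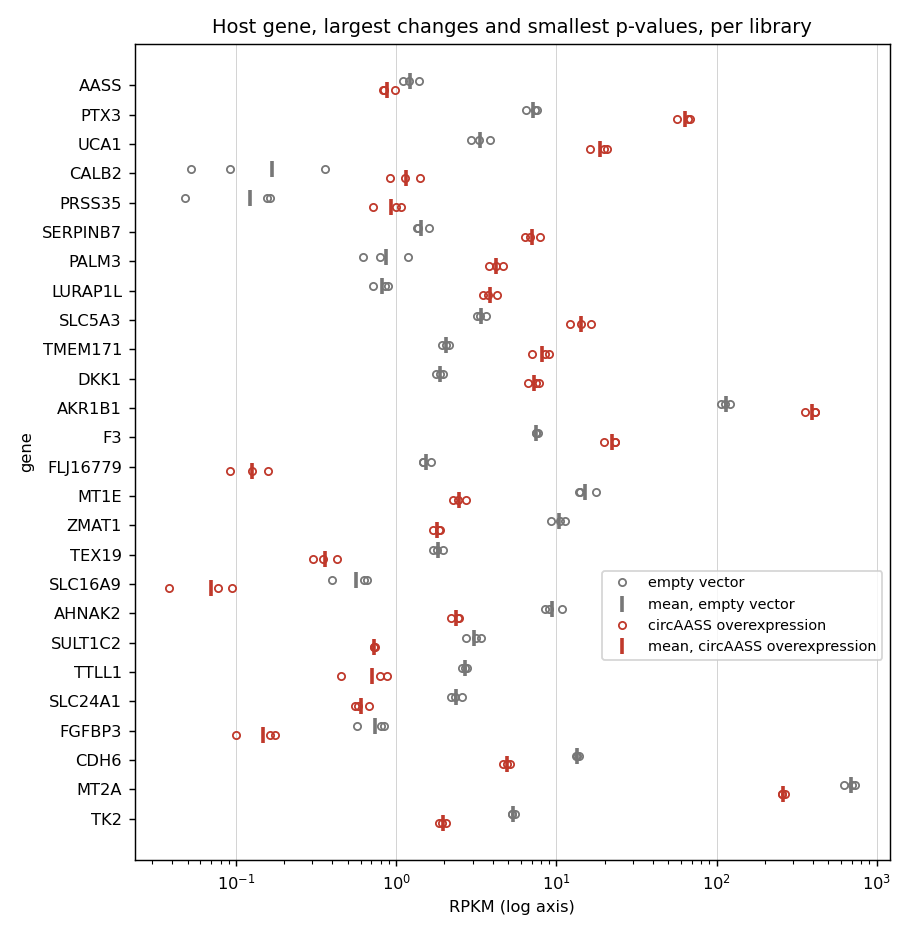
RPKM of AASS and of the genes named by size or by smallest p, on a log axis, in the 3 empty-vector libraries (grey circles) and the 3 circAASS libraries (red circles), with vertical ticks at the group means. In every gene shown the 3 libraries of one group lie wholly above those of the other, with PTX3 at means of 7.11 and 64.0 RPKM and MT2A at 689 and 260.

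Of 19350 genes tested, 6243 (32.26%) changed: 3091 were higher and 3152 lower with the circAASS plasmid (limma, adjusted p under 0.05). A further restriction to changes of at least 2-fold left 244 higher and 352 lower. The median size of change among the changed genes was 0.47 on the log2 scale. The groups did not overlap in 47.9% of all tested genes, where chance gives 10%. Among the changed genes the share was 99.8%, but the test selects such genes, so this share adds no support. Log values correlated across genes at 0.9894 to 0.9912 within groups and at 0.9762 to 0.9800 between them (Pearson, genes not being independent replicates). The split into higher and lower calls depended on the scaling: with library size alone 2159 genes were higher and 4023 lower, and the median log2 fold change of all tested genes moved from -0.01 to -0.08. Without empty-vector library 2 the test gave 2190 higher and 2013 lower genes, the fewest of the 6 fits that left out a library.

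Several RNAs that carry no poly(A) tail, and that are a sign of how clean the poly(A) selection was, differed with the group (chosen after their values were seen). The small nuclear RNA RN7SK went from 38.6 to 127 RPKM, with 668, 576 and 642 reads against 882, 2606 and 2984, and its call was lost without empty-vector library 2 or 3 or circAASS library 2 (adjusted p up to 0.0558) and under 3 other settings (up to 0.129). The signal-recognition RNAs RN7SL1 and RN7SL2 rose by log2 fold changes of 1.02 and 1.56, and RNA5-8S5 by 1.68. Another annotated gene covers 100% of the exon bases of RN7SK and of RN7SL1, and RNAs of these families have many near-identical copies, so that their reads are uncertain. These went with the same groups as every gene group described here. The nuclear RNAs NEAT1 and MALAT1 went the other way, from 15.7 to 7.15 and from 187 to 131 RPKM (log2 fold changes of -1.05 and -0.45). The non-coding RNAs singled out here thus moved in both directions. Whether the poly(A) selection differed between the groups was not tested.

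**Figure D2:**
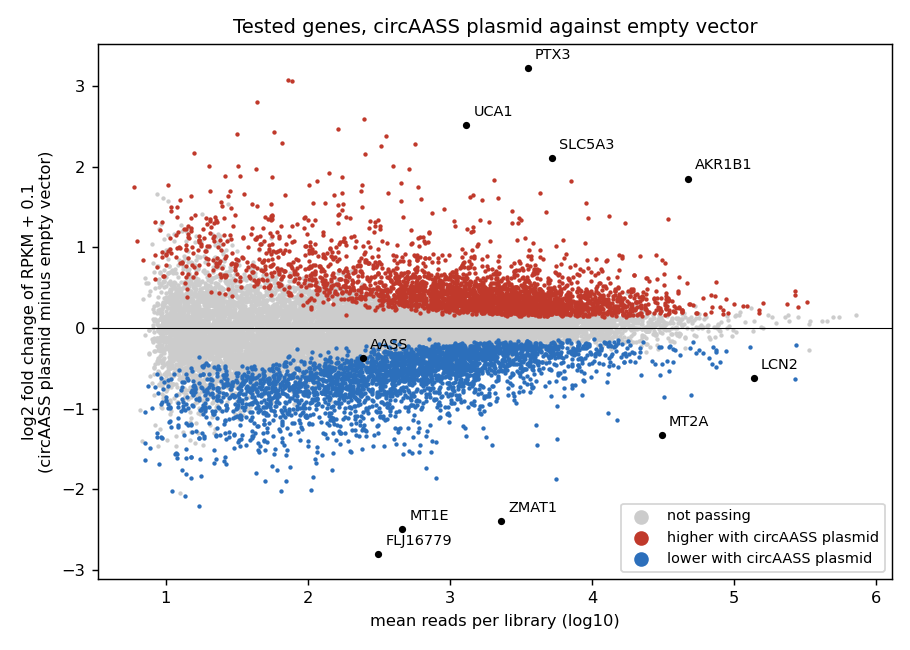
Log2 fold change of RPKM + 0.1, circAASS plasmid minus empty vector, against the log10 of the mean reads per library for the 19350 tested genes, with the 3091 higher genes in red, the 3152 lower genes in blue and those not passing in grey. PTX3, UCA1, SLC5A3 and AKR1B1 lie far above 0, MT2A, MT1E, ZMAT1 and FLJ16779 far below, and AASS lies at -0.37 among the genes not passing.

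The 32 gene lists, fixed before the data were examined, were compared next. Of the 31 lists with at least 5 tested members, 10 passed the competitive test against the other genes (camera, preset correlation of 0.01, adjusted over the lists), 9 higher and 1 lower. With a correlation estimated from the residuals none of the 10 passed, and their adjusted p lay between 0.231 and 0.665. Correlated members do not account for this in every list, since the estimate for cholesterol synthesis was -0.00734, below the preset. What else sets the forms of the test apart was not examined. Of 831 tested members, 344 changed. Below, a list is said to pass or not by camera with the preset correlation alone. Some genes stand in more than 1 list. List members named below beyond the 4 with the smallest p were chosen after their values were seen, because they make up a count of 5 or fewer.

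Targets of the transcription factor ATF4 in the integrated stress response, which covers amino acid synthesis, transport and tRNA charging, gave the smallest p of the lists. Of 35 tested members 26 rose, 3 fell and 6 did not pass, and adjusted over the list alone the counts were also 26 and 3. The list ranked higher than other genes (camera adjusted p = 9.87e-10; adjusted p = 0.231 with an estimated correlation), with a median log2 fold change of 0.44. The cystathionine-cleaving enzyme CTH rose from 0.871 ± 0.120 to 3.06 ± 0.0892 RPKM, the glycyl-tRNA synthetase GARS from 37.0 ± 2.04 to 64.0 ± 1.15, and SHMT2 and MTHFD2, mitochondrial enzymes of folate metabolism, from 19.0 to 28.9 and from 9.09 to 13.7. Other genes lie antisense to 33.2% of the exon bases of MTHFD2. The 3 that fell were VLDLR, ALDH1L2 and PCK2. The calls of ALDH1L2 and PCK2 were lost in 4 and 5 of the 6 fits that left out a library, with adjusted p up to 0.109 and 0.119.

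Chaperones of both the endoplasmic reticulum and the cytosol were among the genes that rose. Of 28 tested targets of ATF6 and XBP1 in the unfolded protein response, 16 rose, 1 fell (ATF6 itself, 4.48 to 3.42 RPKM) and 11 did not pass; adjusted over the list alone 20 rose and 2 fell. The camera adjusted p = 1.54e-05 and the adjusted p = 0.231 with an estimated correlation, at a median of 0.25. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 309 ± 16.0 to 438 ± 26.4 RPKM, with HYOU1 (27.4 to 36.9), DNAJB11 (58.0 to 77.0) and SEC24D (4.67 to 6.03). Other genes cover 23.2% of the exon bases of DNAJB11. Of 23 heat-shock genes 14 rose, 2 fell and 7 did not pass, with 14 and 2 adjusted over the list alone (median 0.28; camera adjusted p = 2.80e-05; adjusted p = 0.341 with an estimated correlation). HSPH1 rose from 36.8 ± 1.41 to 64.9 ± 4.99 RPKM, DNAJA1 from 256 to 330, DNAJB6 from 12.3 to 17.2 and CHORDC1 from 5.87 to 9.34. The 2 that fell were SERPINH1, the collagen chaperone (16.1 to 8.79), and the small heat-shock protein CRYAB (3.98 to 2.63), to which other genes lie antisense over 20.6% of the exon bases.

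Of 32 tested targets of NRF2, the regulator of antioxidant genes, 14 rose, 3 fell and 15 did not pass, and adjusted over the list alone 18 rose and 4 fell (median 0.24; camera adjusted p = 0.00205; adjusted p = 0.231 with an estimated correlation). The epoxide hydrolase EPHX1 rose from 36.0 ± 2.72 to 59.2 ± 3.85 RPKM, ME1 from 6.0 to 10.6 and SQSTM1 from 26.2 to 34.5. The 3 that fell were the export pump ABCC3, from 6.17 ± 0.258 to 2.09 ± 0.154 RPKM, the thioredoxin reductase TXNRD1 (122 to 96.8) and the ferritin chain FTH1 (243 to 206), whose call was lost in 5 of the 6 fits that left out a library (adjusted p up to 0.116). Of 38 tested genes of mitophagy and autophagy, 18 rose, 2 fell and 18 did not pass, with 18 and 4 adjusted over the list alone (median 0.18; camera adjusted p = 0.0242; adjusted p = 0.341 with an estimated correlation). PINK1, a kinase that marks damaged mitochondria, rose from 6.66 ± 0.557 to 15.8 ± 0.466 RPKM, with TFE3 (8.46 to 11.2) and MAP1LC3B (5.77 to 7.41). Antisense genes cover 39.4% of the exon bases of PINK1, 22.0% of those of SQSTM1 and 62.4% of those of FTH1. The 2 that fell were ATG14, lost without empty-vector library 2 (adjusted p = 0.0587), and USP30, lost in 5 of those 6 fits (adjusted p up to 0.0919). With library size alone 11 of these genes rose and 8 fell, and among genes with a mean of at least 1 RPKM the list did not pass (adjusted p = 0.056, the highest over the alternatives, the lowest being 0.00431).

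Immediate-early genes, which respond within minutes to growth factors or stress, rose more often than they fell: 14 of 29 rose, 3 fell and 12 did not pass, with 15 and 3 adjusted over the list alone (median 0.31; camera adjusted p = 0.00196; adjusted p = 0.231 with an estimated correlation). IER5 rose from 9.25 ± 0.652 to 18.8 ± 0.642 RPKM, SPRY2 from 6.08 to 10.3, FOSB from 1.44 to 2.88 and IER3 from 47.8 to 75.4. The 3 that fell were KLF6, JUNB and SGK1, of which SGK1 was lost in 5 of the 6 fits that left out a library (adjusted p up to 0.12). Targets of NF-kB and other inflammatory genes moved both ways: 13 of 35 rose, 9 fell and 13 did not pass, with 16 and 10 adjusted over the list alone, and the list did not pass (median 0.13, camera adjusted p = 0.377). Scaling by library size alone turned the majority, with 10 that rose and 11 that fell (median 0.06). IL6, a cytokine, rose from 17.6 ± 1.15 to 42.4 ± 2.27 RPKM and the NF-kB inhibitor NFKBIA from 54.1 ± 0.737 to 80.9 ± 1.57, while the chemokine CXCL3 fell from 17.3 ± 1.03 to 9.70 ± 0.0900. Antisense genes cover 20.7% of the exon bases of IL6 and 26.5% of those of IER3.

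Interferon-response genes were the only list that passed camera in the lower direction. Directional fry, which does not compare a list with other genes, called further lists lower (fry adjusted p of at most 0.0389). These were lysine degradation, proximal tubule identity, pyroptosis and necroptosis, fatty acid oxidation, and epithelial-mesenchymal transition and fibrosis. Of 41 tested members 12 fell, 3 rose and 26 did not pass, with 13 and 3 adjusted over the list alone (median -0.15; camera adjusted p = 0.0309; adjusted p = 0.341 with an estimated correlation). DDX60 fell from 2.15 to 1.01 RPKM, SAMD9L from 1.41 to 0.653 and OAS3 from 3.80 to 2.50. The 3 that rose were HERC5, DDX58, which encodes the RNA sensor RIG-I, and IFI27. HERC5 was lost without empty-vector library 2 or 3 (adjusted p up to 0.0559) and IFI27 in 4 of the 6 fits that left out a library (adjusted p up to 0.0695). The list itself was lost without circAASS library 1 (adjusted p = 0.0754, the highest over the alternatives, the lowest being 0.0142). Of 20 antigen-presentation genes 3 rose, none fell and 17 did not pass, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.478); those that rose were HLA-E (83.2 to 109 RPKM), TAP2 (7.01 to 9.36) and PSME2 (28.3 to 34.9). With library size alone 2 fell. TAP1 stood at 1.90 and 2.32 RPKM (adjusted p = 0.0652). Another gene overlaps 32.3% of the exon bases of TAP2.

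The list of tubular injury markers did not move together. Of 24 tested members 8 rose, 9 fell and 7 did not pass, with 9 and 9 adjusted over the list alone; the median was -0.02 while the mean was 0.04 and the test pointed up (camera adjusted p = 0.916). Besides AKR1B1, the matrix protein TNC rose from 8.65 ± 0.238 to 14.1 ± 0.626 RPKM. IGFBP7 fell from 83.0 ± 4.35 to 47.1 ± 4.51 RPKM and the cytokine IL18 from 6.13 ± 0.351 to 2.25 ± 0.457. Of the injury markers in common use, chosen here after their values were seen, LCN2 (NGAL) fell from 2108 ± 151 to 1307 ± 132 RPKM (log2 fold change -0.62, SE 0.09, adjusted p = 0.00264) and HAVCR1 (KIM-1) from 28.5 ± 0.370 to 20.4 ± 2.43 (log2 fold change -0.42, adjusted p = 0.00584). Of 20 tested genes of proximal tubule identity, 7 fell, 2 rose and 11 did not pass, with 7 and 4 adjusted over the list alone (median -0.07, camera adjusted p = 0.259). With CDH6 fell the glucose transporter SLC5A2 (3.85 to 1.87 RPKM) and the sodium-proton exchanger SLC9A3 (2.67 to 1.18). Among those that rose was the transcription factor PAX8 (25.0 ± 1.22 to 42.3 ± 2.64). Antisense genes cover 40.7% of the exon bases of SLC5A2, and SLC9A3 shares 41.9% of its own with a gene on the same strand.

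Epithelial, matrix and YAP genes were mixed, and none of the 3 lists passed. Of 22 epithelial junction and keratin genes 5 rose, 3 fell and 14 did not pass, with 5 and 3 adjusted over the list alone (median 0.10, camera adjusted p = 0.293). Those that rose were the tight-junction genes CLDN1 (51.0 ± 1.23 to 87.1 ± 5.51 RPKM) and OCLN and the keratins KRT18 (79.3 to 107), KRT7 and KRT8. Those that fell were CLDN2 (4.57 ± 0.934 to 1.43 ± 0.157), the splicing factor ESRP1 (0.139 to 0.0123) and EPCAM, which was lost in 5 of the 6 fits that left out a library (adjusted p up to 0.106). ESRP1 lay near the floor, at 0 RPKM in circAASS library 1. The size of its change is set by the pseudocount, being -1.07 as reported, -2.35 with 0.02 RPKM and -0.17 with 1. Of 36 genes of epithelial-mesenchymal transition and fibrosis 10 fell, 6 rose and 20 did not pass, with 12 and 7 adjusted over the list alone (median -0.07, camera adjusted p = 0.259). The basement-membrane collagen COL4A1 fell from 158 ± 7.51 to 84.5 ± 6.35 RPKM, ITGB1 from 295 ± 10.3 to 200 ± 5.38, COL5A1 from 19.7 to 10.5 and LTBP2 from 7.90 to 4.24. Of 23 YAP and TEAD targets 4 rose (F3, AJUBA, CYR61 and ANKRD1), 4 fell (IGFBP3, MYOF, AMOTL1 and PTPN14) and 15 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.819). The median was 0.05 and -0.03 with library size alone, and PTPN14 was lost in 5 of those 6 fits (adjusted p up to 0.145).

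Targets of the hypoxia-inducible factors, tested after 12 h of reoxygenation in both groups, also moved both ways. Of 41 members 9 rose, 10 fell and 22 did not pass, with 9 and 11 adjusted over the list alone; the median was -0.07 and the mean -0.03 while the test pointed up (camera adjusted p = 0.916). VEGFA rose from 7.41 ± 0.439 to 12.0 ± 0.296 RPKM, the hexokinase HK1 from 17.8 ± 0.420 to 26.1 ± 0.988 and the collagen hydroxylase P4HA2 from 29.5 to 38.5. The transcriptional repressor BHLHE40 fell from 11.5 ± 0.378 to 5.52 ± 0.175 RPKM. With library size alone 6 rose and 13 fell.

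Cholesterol synthesis genes rose more often than they fell. Of 25 members 12 rose, 1 fell (PMVK, 12.6 to 8.84 RPKM) and 12 did not pass, with 13 and 1 adjusted over the list alone (median 0.18; camera adjusted p = 0.00295; adjusted p = 0.231 with an estimated correlation). The squalene epoxidase SQLE rose from 13.5 ± 0.355 to 19.3 ± 0.237 RPKM, INSIG1 from 8.93 to 13.7, CYP51A1 from 14.1 to 19.1 and ACAT2 from 19.9 to 30.7. Antisense genes cover 52.3% of the exon bases of ACAT2, and genes on the same strand share 79.4% of those of CYP51A1.

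The remaining metabolic lists did not pass. Of 29 genes of fatty acid oxidation 5 rose, 6 fell and 18 did not pass, with 5 and 7 adjusted over the list alone (median -0.03, camera adjusted p = 0.506). ACADS, a short-chain acyl-CoA dehydrogenase, fell from 2.03 ± 0.103 to 0.728 ± 0.0570 RPKM, CPT2 from 0.662 to 0.228, ETFB from 9.14 to 5.87 and HADH from 6.95 to 4.99. The 5 that rose were ETFA, HADHA, ACSL3, ETFDH and PPARA. HADHA was lost without empty-vector library 3 (adjusted p = 0.0593), and ACSL3, ETFDH and PPARA in 4, 4 and 5 of the 6 fits that left out a library (adjusted p up to 0.131). Scaled by library size alone, 1 rose and 9 fell. Of 18 genes of lysine degradation, the pathway of AASS, 7 fell, 2 rose (ACAT2 and HADHA) and 9 did not pass, with 8 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.373). EHHADH fell from 1.37 to 0.695 RPKM and DLST from 17.4 to 14.3. Of 60 nuclear genes of oxidative phosphorylation 9 rose, 3 fell (NDUFB5 and SDHC among them) and 48 did not pass, with 8 and 3 adjusted over the list alone (median 0.06, camera adjusted p = 0.136). With library size alone 4 rose and 5 fell, at a median of -0.01, and SDHC was lost in 3 of those 6 fits (adjusted p up to 0.0725). Of 13 genes of the mitochondrial genome MT-ND1 and MT-ND2 rose (4853 to 6197 and 4352 to 5699.6 RPKM), none fell and 11 did not pass, with 2 and 0 adjusted over the list alone (median 0.13, camera adjusted p = 0.164). MT-ND1 was lost without empty-vector library 1, 2 or 3 (adjusted p up to 0.0744).

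No cell-death list passed camera. Directional fry, which makes no comparison with other genes, called ferroptosis and apoptosis higher (fry adjusted p = 0.0043 and 0.00486). It called pyroptosis and necroptosis lower (fry adjusted p = 0.00486). Of 28 ferroptosis genes 10 rose, 4 fell and 14 did not pass, with 12 and 5 adjusted over the list alone (median 0.06, and -0.01 with library size alone; camera adjusted p = 0.136). SAT1, which breaks down polyamines, rose from 159 ± 2.96 to 285 ± 3.67 RPKM, the iron-sulphur protein CISD1 from 3.66 to 6.70, and SLC7A11 and SLC3A2, the subunits of the cystine-glutamate exchanger, from 0.888 to 1.86 and from 10.6 to 14.4. The 4 that fell were DHODH, SLC40A1, FTH1 and SLC11A2. SLC11A2 was lost in 5 of the 6 fits that left out a library (adjusted p up to 0.148), and SLC40A1 with no filter on low counts (adjusted p = 0.087). Of 35 apoptosis regulators 10 rose, 4 fell and 21 did not pass, with 11 and 6 adjusted over the list alone (median 0.05, camera adjusted p = 0.293). The pro-apoptotic gene PMAIP1 rose from 21.1 ± 0.517 to 33.2 ± 2.14 RPKM, and BIRC3 (8.53 to 11.4), BIRC5 (21.4 to 25.7) and AIFM1 (23.5 to 29.2) rose too. The 4 that fell were CASP6, TRADD, BOK and CASP8, of which TRADD, BOK and CASP8 were lost in 3, 4 and 4 of those 6 fits (adjusted p up to 0.0906). Scaled by library size alone, 7 rose and 8 fell, at a median of -0.02.

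Of 11 tested genes of pyroptosis and necroptosis 5 fell, 1 rose (CYLD, a deubiquitinase, 3.57 to 5.43 RPKM) and 5 did not pass, with the same counts adjusted over the list alone (median -0.26, camera adjusted p = 0.123). Those that fell were IL18, the gasdermin genes DFNA5 (GSDME, 3.80 to 2.61) and GSDMD (3.76 to 2.80), RIPK1 (12.9 to 10.2) and NLRP1, which was lost in 4 of the 6 fits that left out a library (adjusted p up to 0.0636). Of 27 p53 targets 4 rose (PMAIP1, TIGAR, GDF15 and CCNG1), 4 fell (XPC, FAS, DDB2 and RRM2B) and 19 did not pass, with the same counts adjusted over the list alone; the median was -0.06 and the mean -0.03 while the test pointed up (camera adjusted p = 0.916). DDB2 was lost without empty-vector library 3 (adjusted p = 0.0544), RRM2B in 4 of those 6 fits (adjusted p up to 0.0898) and CCNG1 with library size alone (adjusted p = 0.0507), where 3 rose and 6 fell. Overlapping genes cover 42.6% of the exon bases of TIGAR on its own strand and 30.4% of those of XPC on the other.

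Of the cell-cycle lists, the mitotic genes ranked higher than other genes. Of 40 genes of the G2 and M phases 17 rose, 2 fell and 21 did not pass, with 18 and 2 adjusted over the list alone (median 0.14; camera adjusted p = 1.54e-05; adjusted p = 0.433 with an estimated correlation). AURKA, a mitotic kinase, rose from 21.5 ± 0.856 to 33.6 ± 3.34 RPKM, ECT2 from 29 to 41.6, KIF20A from 31.0 to 41.1 and CDC20 from 17.8 to 24.7. The 2 that fell were HMMR and KIF11, and KIF11 was lost in 4 of the 6 fits that left out a library (adjusted p up to 0.105). Of 35 S-phase genes 6 rose, 4 fell (CCNE2, GINS1, MCM2 and TIPIN) and 25 did not pass, with 6 and 3 adjusted over the list alone (median 0.01, camera adjusted p = 0.916). With library size alone 3 rose and 11 fell, at a median of -0.06. GINS1, MCM2 and TIPIN were lost in 3, 3 and 5 of those 6 fits (adjusted p up to 0.141). Antisense genes cover 37.1% of the exon bases of CCNE2 and 23.6% of those of MCM2, and a gene on the same strand shares 21% of those of TIPIN. The difference between the G2/M and S lists was not tested. Of 10 tested histone genes 3 rose (HIST1H2BD, HIST1H2BK and HIST1H2AC), none fell and 7 did not pass, with 3 and 0 adjusted over the list alone (median 0.22, camera adjusted p = 0.293). Each of the 3 was lost in at least 4 of those 6 fits (adjusted p up to 0.13), and near-identical histone copies leave their reads uncertain.

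Of 73 cytosolic ribosomal protein genes 10 rose, none fell and 63 did not pass, and adjusted over the list alone 1 rose (median 0.12; camera adjusted p = 3.27e-05; adjusted p = 0.665 with an estimated correlation). RPL23A stood at 807 ± 30.3 and 925 ± 9.14 RPKM, RPS29 at 1.80 and 2.25 and RPL37A at 25.5 and 28.2, all higher past the threshold. With library size alone 2 rose, RPS29 was lost without empty-vector library 2 or circAASS library 2 (adjusted p up to 0.0598), and RPL37A in 4 of the 6 fits that left out a library (adjusted p up to 0.0974). The many processed pseudogenes of this family leave the assignment of its reads uncertain.

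Few markers of other cell types changed. Of 8 tested fibroblast markers 2 rose, FBLN1 (6.65 to 8.11 RPKM) and S100A4 (0.571 to 1.56), with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.293). Of 5 tested endothelial markers ROBO4 rose (0.0514 to 0.122 RPKM) and none did adjusted over the list alone; the median was -0.03 while the mean was 0.09 and the test pointed up (camera adjusted p = 0.916), and ROBO4 was lost in 5 of the 6 fits that left out a library (adjusted p up to 0.129). Of 5 tested leukocyte markers CSF1R fell (0.844 to 0.459 RPKM), also adjusted over the list alone (median -0.16, camera adjusted p = 0.725), and was lost in 4 of those 6 fits (adjusted p up to 0.0688). Of 4 tested markers of the distal nephron SCNN1A fell (0.602 to 0.219 RPKM), also adjusted over the list alone, and 4 members were too few for the list test (median 0.10, mean -0.11).

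**Figure D3:**
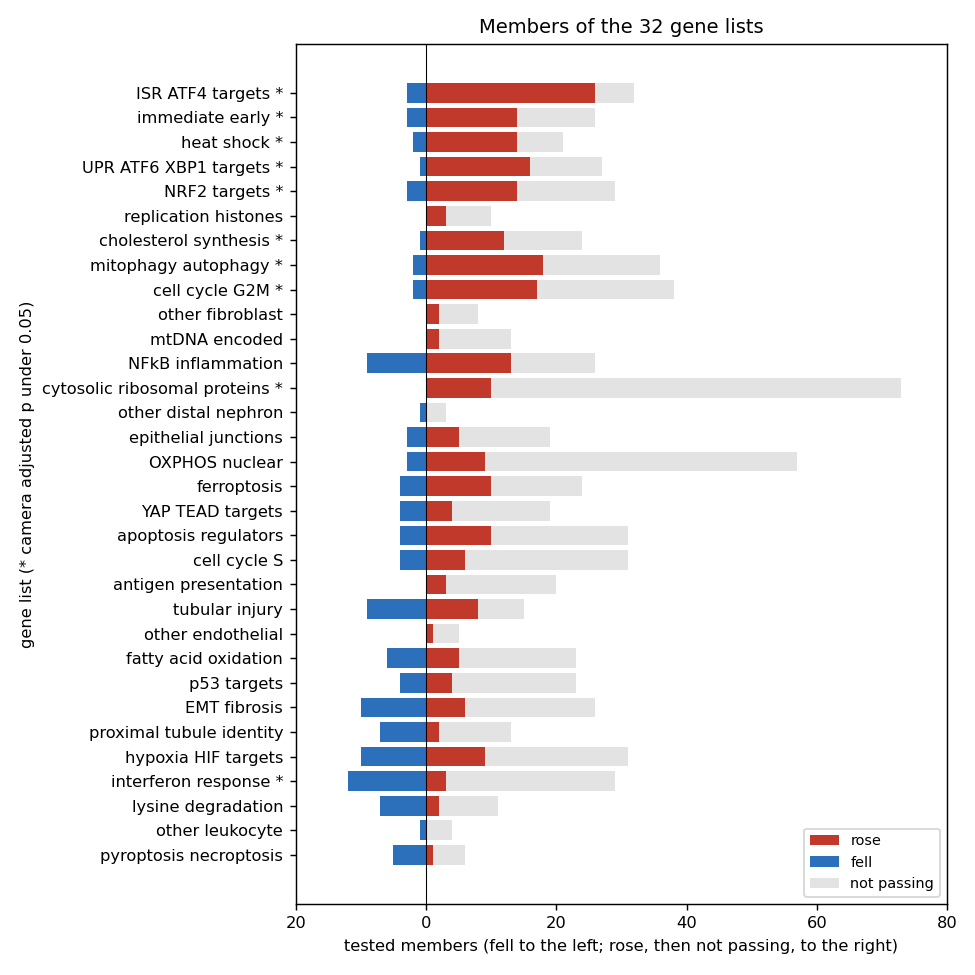
Number of tested members of each of the 32 gene lists that fell (blue, to the left of 0), rose (red, to the right) or did not pass (grey, stacked on the risen ones), ordered by median log2 fold change, with an asterisk at the 10 lists with a camera adjusted p under 0.05. The ATF4 target list has 26 of 35 members in red, and the interferon list, the only asterisk with more blue than red, has 12 of 41 in blue.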

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

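The pseudocounts, the mean-RPKM filter and the GC and length correction were chosen after seeing the data. The other settings were not, except that voom used recovered reads, which were worked out once the values proved to be RPKM. A Wald test with DESeq2 was not run, since the deposited values are not counts, nor was it tried on the recovered reads. Changed genes numbered 4394 with no filter to 7547 with voom and 4203 to 5697 with a library left out, and no gene changed in both a setting and the reported fit had opposite signs. The lower genes numbered 2084 with no filter, which tests more genes, and 2013 to 2906 with a library left out, the fewest without empty-vector library 2. A fold of at least 2 left 596 genes (244 higher, 352 lower) and an adjusted p under 0.01 left 2985 (1543 higher, 1442 lower), both by construction. AASS passed with library size alone (-0.44), CPM above 1 (-0.38), voom (-0.39), and GC and length removed without (-0.37) or with the block (-0.37); the cause was not tested. With a library left out its log2 fold change was -0.28 to -0.44 and it did not pass.

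Of the 10 lists, 0 passed with an estimated correlation. Over all 31 tested lists, fry called 18 in its directional form and 29 in either direction. Those tests ask whether a list's genes move, on balance, one way or at all and do not compare them with other genes. Among the 10, the ribosomal protein list passed neither form (fry adjusted p = 0.157 and 0.0609). Under the 21 other settings 8 of the 10 always passed; the interferon and autophagy lists were each lost once. Of 196 genes other than AASS followed through the settings, 157 had no call lost under any setting, 37 lost theirs with a library left out, 1 (TAP1) gained one and 0 reversed. The pseudocount moved 19 low genes by over 1.5 times. The replicate block gave 5428 changed genes, 5877 with GC and length removed, and ended no list's call. The labels give no pairing beyond the repeat numbers, and no sign of pairing was seen. Deviations of same-numbered libraries correlated at -0.01, -0.02 and 0.02, and 1 of 6 libraries correlated best with its own number. With 3 libraries per group this cannot exclude pairing, so no conclusion is drawn from the lower count with the block.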

Other observations

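All tests here were chosen after the result was seen, except those on glucocorticoid targets, on GDPD5 and on other splits of the libraries.

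Besides AKR1B1 and SLC5A3, 3 transporters of osmolytes or amino acids were singled out after their values were seen; no list of such genes was fixed beforehand or tested. The taurine transporter SLC6A6 rose from 6.65 ± 0.390 to 10.9 ± 1.1 RPKM, the betaine transporter SLC6A12 from 0.0198 ± 0.0105 to 0.165 ± 0.0658 and the neutral amino acid transporter SLC38A2 from 22.1 ± 1.30 to 55.7 ± 6.76, with log2 fold changes of 0.77, 1.15 and 1.40 (limma, adjusted p of at most 0.00583), higher in all 3 circAASS libraries than in any empty-vector library. The size for SLC6A12 is set by the pseudocount, being 2.25 with 0.02 RPKM, 0.36 with 0.5 and 0.20 with 1. Of 2 zinc transporters, likewise singled out for their values, the exporter SLC30A1 fell from 3.06 ± 0.282 to 1.69 ± 0.349 RPKM and the importer SLC39A10 rose from 5.0 to 12.4, with log2 fold changes of -0.77 (SE 0.14) and 1.36 (SE 0.08). ATF4 itself rose from 101 ± 3.68 to 136 ± 8.70 RPKM. Of the 6 tested metallothioneins MT1F (1.85 to 0.505 RPKM) and MT1X (1.49 to 0.660) fell besides MT2A and MT1E, while MT1M stood at 0.746 and 0.443 and MT1A at 0.897 and 1.15, neither passing (adjusted p = 0.147 and 0.422).

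The lower values of these 4 metallothioneins were first set against reads shared between copies. MT2A took 814, 916 and 956 RPM (reads scaled to library size) with empty vector and 336, 345 and 331 with the circAASS plasmid. The other 10 metallothionein genes of the table together took 21.3, 22.2 and 26.5 RPM against 5.46, 5.69 and 5.74. They thus changed by -17.7 RPM while MT2A changed by -558, which argues against MT2A having fallen because its reads passed to its copies. A fixed share of MT2A reads counted for the copies in both groups would fall along with MT2A. Such a share is not excluded by these sums. For MT1E, MT1F and MT1X sharing stays open: the sum without MT2A had a log2 ratio of -2.05, but MT2A outweighs these genes and its own fall would hide reads gained from them. Less transcription driven by zinc stays open: it would lower SLC30A1 and raise SLC39A10, but their log2 fold changes, 2.13 apart, are the values for which both were singled out and lend it no support. Lower glucocorticoid signalling stays open too, since FKBP5 fell (-0.45), TSC22D3 stood at -0.16 without passing and PER1 rose (0.82), leaving 1 of the 3 targets with an interval above -0.2. An effect of circAASS, the difference the design names, is untested against either.

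The rise of these 5 osmolyte and amino acid genes could come from overlapping genes, from a GC or length trend or from an osmotic response. The 5 genes were chosen because they rose, so their rise is no test of the group. Overlap is argued against only for AKR1B1 and SLC38A2, the 2 members with no overlapping exon, which rose. Other genes lie antisense to 2.9% of the exon bases of SLC6A6 and 1.1% of those of SLC6A12, and reads from them were not tested for. After the GC and length trend was removed the median of the members was still 1.4, which argues against that trend. For SLC5A3 itself, a fixed share of reads from MRPS6, which shares exon bases with it, would raise it by no more than MRPS6 rose (1.68); the log2 ratio of SLC5A3 to MRPS6 was higher by 0.46 with the circAASS plasmid (95% interval 0.26 to 0.66, Welch t), which argues against such reads as the whole of the rise. A part is not excluded. An osmotic response cannot be told apart from its absence by GDPD5, which high salt lowers in kidney cells: its log2 fold change was -0.13 (95% interval -0.47 to 0.22, adjusted p = 0.549), which excludes neither. An effect of circAASS is untested.

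Antigen-receptor segments, which a kidney epithelial line does not rearrange, had reads in all 6 libraries: 288 such genes took 195 to 249 RPM, with IGKV3-20 at 22.6 to 30.9 RPKM and TRBV20-1 at 49.5 to 65.2, and of 144 tested 15 were higher and 1 lower with the circAASS plasmid. RNA of lymphocytes is argued against, since 10 lymphocyte markers together had at most 0.22% as many reads as the segments in any library. Reads from an amplified antigen-receptor library, for example of another project on the same sequencer, remain a candidate source: kappa variable segments summed to at least 6.86 times the RPKM of the constant segment IGKC in every library, where whole transcripts hold as many of either. No biological explanation within the HK-2 cells was tested.

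Of the 10 splits of the 6 libraries into 3 and 3, the real one alone (1 of 10) gave as many as 6243 changed genes, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.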
